A study of Mus musculus with 23 samples.

How the data were processed

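The series measured the occupancy of mouse ribosomal DNA (rDNA) by the RNA polymerase I machinery with ChIP-seq in 23 libraries. The cells were the mouse ER-HoxA9 line, a myeloid progenitor line kept immature by an oestrogen receptor fusion of HOXA9, with an FKBPV-FLAG tag integrated at the Cebpa locus so that the tagged CEBPA protein is degraded on addition of dTAGV-1. Per the labels' protocols, cells received 500 nM dTAGV-1 for 4, 8 or 10 h, and the 0 h cells received DMSO for as long as the longest treatment. RPA194, the largest subunit of RNA polymerase I, was measured at 0, 4, 8 and 10 h. RRN3, TAF1B and UBTF were measured at 0 and 8 h. Each antibody and time had 2 libraries. Input, IgG and CEBPA-FLAG had 1 library each. Per the labels' protocols, the same number of cells per sample was fixed with 1% formaldehyde for 15 min, chromatin was cut with MNase and sonicated, 50 ng of Drosophila chromatin was added as spike-in together with an antibody to the Drosophila histone H2Av, and 10 µg of antibody was used for each pulldown. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

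The deposited values of the RPA194, RRN3, TAF1B and UBTF tables are signal per nucleotide, which the authors normalized to the reads of the Drosophila spike-in pulldown and smoothed over 80 nt on each side, per the file headers. Reads were mapped to the GenBank mouse rDNA unit of 45306 nt, per the file headers, and the last part of the intergenic spacer was placed upstream of the 47S start site with negative positions. These tables hold 45147 positions, from -3224 to 41922, so 159 nt of the spacer are not covered. The values of the Input, IgG and CEBPA-FLAG table are described as normalized mapping signal over positions 1 to 45306, per the file headers, and how the authors normalized them is not given in the sources used here. In that table each column had a median of 1 and 100% of its values were whole multiples of 1 step (within 0.01 of a step), equal to the median divided by 59 in Input, 68 in IgG and 26 in CEBPA-FLAG. Trimmomatic, Bowtie2, SAMtools and Picard, and the builds mm9 and dm3, are named without versions or roles in the submitters' processing notes. How reads that map to more than 1 copy of the repeat were counted, and the spike-in factors of each library, are not given in the sources used here.

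The headers describe the same processing for the 4 antibodies, but the values differ in kind. Of the differences between neighbouring positions, 100% in RRN3 and TAF1B were whole multiples of the smallest one in the library (within 0.01 of it), and the signal of the intergenic spacer followed Input (Pearson's r from 0.661 to 0.735 per library over 241 bins of 100 nt, which are not independent). In RPA194 and UBTF at most 5.77% were whole multiples, where chance gives about 2%, and r lay between -0.16 and 0.17. Whether these values were also divided by Input at each position is not given in the sources used here. Levels along the unit depend on that, while a ratio between libraries at the same position does not if they shared the Input. Levels and tests between times were therefore kept within a table, and levels were not compared between antibodies. Across tables, log2 changes at 8 h were subtracted, and the RPA194 signal was read at positions taken from the TAF1B and CEBPA-FLAG signals.

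Signal was averaged over 10 regions fixed before the data were examined, with rounded boundaries taken from general knowledge of the GenBank layout and counted in nucleotides from the 47S start site. These are the 47S promoter (the last 300 nt of the unit and the first 100 nt), the 47S transcribed region (200 to 13000), the 5' external transcribed spacer (200 to 3900), 18S (4100 to 5800), the internal spacers with 5.8S (5900 to 8100), 28S (8200 to 12000), the terminator and downstream (13000 to 15000), the intergenic spacer as background (16000 to 40000), the spacer promoter (42000 to 44000, of which the tables cover 42082 onwards) and the enhancer repeats (44000 to 400 nt before the end). Changes are on the log2 scale of the region mean plus a pseudocount of 1% of the antibody's mean signal over the unit, which understates changes of low regions. Errors are SD over 2 libraries or the pooled SD of log2 values within times. The sequencing depth of the antibody libraries is not given in the sources used here, and no interval for counting error is given for them. For RRN3 and TAF1B, where differences were whole multiples of 1 step, a depth may be recoverable, which was not tried. For CEBPA-FLAG, exact Poisson intervals at 95% treat 1 step as 1 fragment and cover counting error only.

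RPA194 at 4, 8 and 10 h (6 libraries) was compared with 0 h (2 libraries) by a two-sided exact permutation test over 28 splits, whose smallest p is 0.0357, with Benjamini-Hochberg adjustment over the 10 regions. The relation to hours was tested over all 2520 orders of the time labels. A comparison of 2 with 2 libraries has 6 splits, so the exact permutation test cannot go below p = 0.333, and values, both libraries and the range of the 4 ratios of a treated to a control library are the result. Differences between antibodies in the 8 h change were tested over 36 joint splits, whose smallest p is 0.0556, adjusted over 6 pairs. The unit was also cut into 45 bins of 1000 nt, which were tested with limma at an adjusted p of 0.05. Neighbouring bins of a library are not independent, so these adjusted p-values are too small. For RRN3, TAF1B and UBTF, limma gave all bins of an antibody 1 shared SE, which is not the error of a single bin. Simulated data had independent noise in each bin (SD 0.1), unlike the smoothed and correlated bins here, so recovery in them is not the power in these data. On simulated data limma recovered 100% of 10 bins changed by 1 on the log2 scale among the 45 bins of each antibody's 8 h comparison. With a shift shared by all bins of a library (SD 0.3), it recovered 65.2% in the RPA194 comparison, 62.8% in RRN3, 68.0% in TAF1B and 77.4% in UBTF. It then called 3.77%, 17.9%, 9.83% and 16.6% of unchanged bins in the same order. The exact test of 2 against 6 libraries gave p at or below 0.05 in 3% of 2000 simulations with no effect. That rate follows from the 28 splits and the independent simulated values, so it checks the calculation and not the libraries here.

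The text names the fixed regions, the 3 bins with the largest rise and the 3 with the largest fall past the limma threshold per antibody, and the 3 bins with the highest ratio of CEBPA-FLAG to IgG. Further positions are named as chosen after their values were seen. The alternatives were spacer means set equal between libraries (called spacer-equalized scaling), the library's own spacer mean subtracted, medians in place of means, boundaries moved by 200 nt, no pseudocount or 10% of the mean, positions with Input below 10% of its median left out, bins of 500 and 100 nt, a threshold of 0.01, a replicate block and each replicate left out. No 2 libraries of an antibody held an identical bin value. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.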

Results

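The data comprised ChIP-seq signal along the mouse rDNA repeat, the tandem unit that RNA polymerase I transcribes into the 47S precursor of 18S, 5.8S and 28S ribosomal RNA. The study asked how degradation of CEBPA, a transcription factor of the myeloid lineage, affects the machinery that transcribes rRNA. Of the 23 libraries, 8 were of RPA194 (0, 4, 8 and 10 h of dTAGV-1, 2 per time), 4 each were of RRN3, TAF1B and UBTF (0 and 8 h, 2 per time), and Input, IgG and CEBPA-FLAG had 1 each. Values of the 20 libraries of these 4 antibodies are the authors' spike-in normalized signal, and their sequencing depth is not given in the sources used here. The Input, IgG and CEBPA-FLAG values are a normalized signal with a median of 1 per library, equal to 59, 68 and 26 of the smallest steps between values, and its normalization is not given in the sources used here. The number of libraries, n, is 2 per time wherever a mean ± SD is given. Positions count from the 47S start site in the GenBank mouse rDNA unit of 45306 nt.

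The libraries at 0 h showed where each factor sat on the unit. RPA194, the largest subunit of RNA polymerase I, covered the 47S transcribed region at 102.9 ± 5.84 and rose along it, from 46.2 ± 0.41 in the 5' external transcribed spacer through 88.5 ± 3.38 in 18S to 139.4 ± 12.2 in 28S. Its level in the intergenic spacer was 2.75 ± 1.51. Whether the RPA194 and UBTF values were also divided by Input at each position is not given in the sources used here, so their levels along the unit depend on that. RRN3, which links polymerase I to the promoter complex, was highest at position -131 and averaged 37.1 ± 3.33 in the 47S promoter, against 1.62 ± 0.050 in the intergenic spacer. TAF1B, a subunit of the promoter selectivity factor SL-1, averaged 56.2 ± 13.7 in the 47S promoter and had its highest point in the spacer promoter, at -2030 in replicate 1 and -2032 in replicate 2. UBTF, an HMG-box protein that holds active rDNA open, spread over the enhancer repeats (47.2 ± 16.1), the 47S promoter (27.3 ± 9.11) and the transcribed region (37.0 ± 12.7), against 0.85 ± 0.24 in the intergenic spacer.

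**Figure D1:**
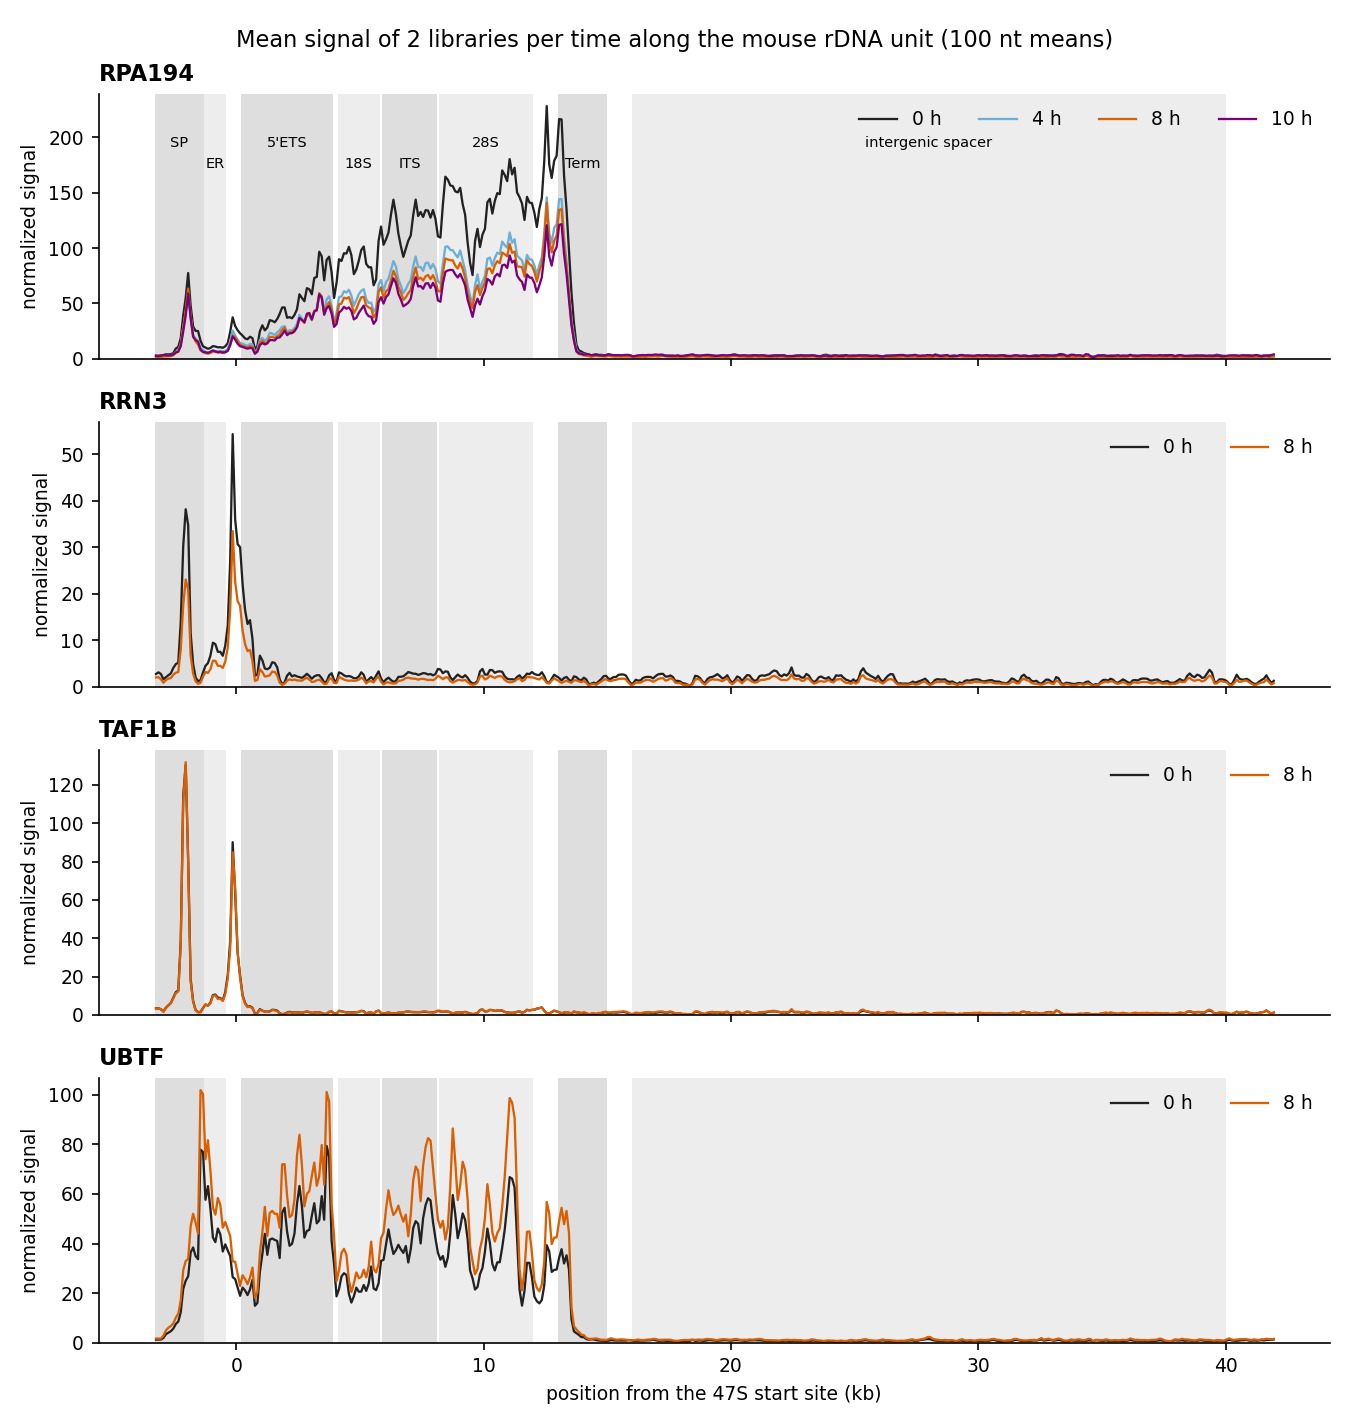
Mean signal of 2 libraries per time (y axes, spike-in normalized signal, separate scale per antibody) in 100 nt means against position from the 47S start site (x axis, kb), with shaded spacer promoter (SP), enhancer repeats (ER), 5' external transcribed spacer (5'ETS), 18S, internal spacers (ITS), 28S, terminator (Term) and intergenic spacer. The RPA194 lines at 4, 8 and 10 h lie below the 0 h line across the transcribed region, where the mean went from 102.9 at 0 h to 52.5 at 10 h.

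To ask whether polymerase I leaves rDNA when CEBPA is degraded, RPA194 was compared between treated and 0 h libraries. RPA194 fell across the whole transcribed region: the mean went from 102.9 ± 5.84 at 0 h to 65.1 ± 4.99 at 4 h, 59.1 ± 3.97 at 8 h and 52.5 ± 1.12 at 10 h. The log2 changes were -0.66 at 4 h, -0.80 at 8 h and -0.97 at 10 h, with pooled SDs of 0.097, 0.089 and 0.062, and 63.2%, 57.4% and 51.0% of the 0 h level was left. Relative to the intergenic spacer of the same library, the transcribed region stood at 25.9 and 63.9 at 0 h, 32.6 and 23.0 at 4 h, 28.6 and 38.0 at 8 h and 19.0 and 17.0 at 10 h. Setting spacer means equal between libraries gave log2 changes of -0.57, -0.30 and -1.17 (pooled SDs 0.70, 0.68 and 0.66), without a stepwise order over 4, 8 and 10 h. The 18S part went to 41.7 ± 1.55 at 10 h (log2 change -1.08, pooled SD 0.054), the 28S part to 70.2 ± 0.89 (log2 change -0.99) and the 5' external transcribed spacer to 26.1 ± 1.24 (log2 change -0.82). At the 47S promoter RPA194 fell from 29.3 ± 4.37 to 20.0 ± 2.17 at 4 h, 17.2 ± 1.33 at 8 h and 15.8 ± 0.25 at 10 h. All 6 treated libraries lay below both 0 h libraries in 9 of the 10 regions, and the exception was the intergenic spacer.

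Over the 6 treated libraries together, the log2 change was -0.81 in the transcribed region (ratio 0.571, with ratios of single libraries from 0.483 to 0.694) and -0.72 in the 47S promoter (ratio 0.605, from 0.483 to 0.820). Each had an exact permutation p of 0.0357, two-sided and the smallest that 28 splits allow, and an adjusted p of 0.0397 over the 10 regions. The same p-values held for the 5' external transcribed spacer (-0.74), 18S (-0.86), the internal spacers with 5.8S (-0.82), 28S (-0.82), the terminator and downstream (-0.70), the enhancer repeats (-0.73) and the spacer promoter (-0.48). All regions were read from the same libraries, and several lie within the transcribed region. The same split gave the smallest p in each, and the adjusted p follows from that shared value. These regions are therefore not separate evidence. The intergenic spacer changed by -0.12 with a pooled SD of 0.45 (exact permutation p = 0.643). By time, the spacer changed by -0.090 at 4 h, -0.46 at 8 h and 0.18 at 10 h (pooled SDs 0.62, 0.55 and 0.54). Its libraries were at 3.82 and 1.67 at 0 h and from 1.63 to 3.04 in the treated cells. With spacer means set equal between libraries the calls ended in the transcribed region (-0.68, pooled SD 0.52, exact permutation p = 0.214) and in the 47S promoter (-0.60, exact permutation p = 0.250). Leaving out either 0 h library leaves 7 splits, whose smallest p is 0.143, and the change in the transcribed region was then -0.87 without replicate 1 and -0.75 without replicate 2.

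**Figure D2:**
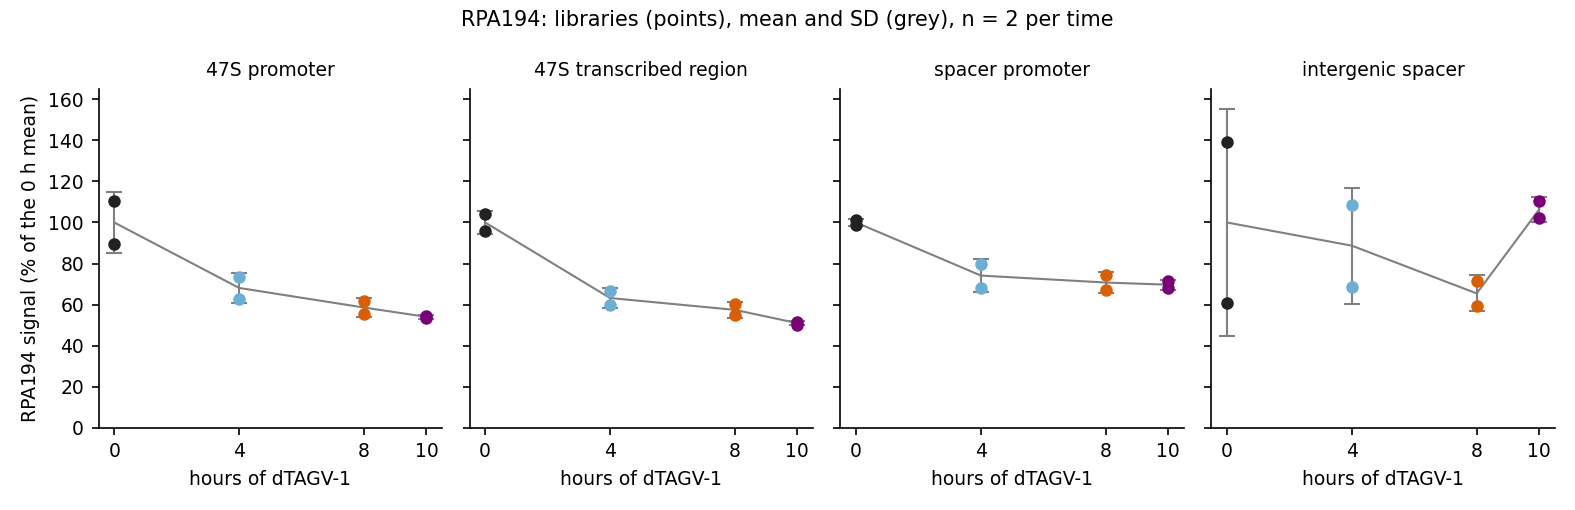
RPA194 signal as a percentage of the 0 h mean (y axes) against hours of dTAGV-1 (x axes) in 4 regions; points are libraries, and the grey line and bars are the mean and SD of 2 libraries. In the transcribed region 51.0% of the 0 h level was left at 10 h and in the spacer promoter 69.7%, and the intergenic spacer libraries at 0 h stood at signals of 3.82 and 1.67.

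The level of RPA194 in the transcribed region went down with hours of treatment. Over the 8 libraries, Pearson's r between hours and the log2 signal was -0.94 (exact permutation p = 0.000794) and Spearman's rho was -0.93 (exact permutation p = 0.00317); this was the only relation to hours tested. Without the 2 libraries at 0 h, the farthest from the median time, r over the 6 treated libraries was -0.87 (exact permutation p = 0.0444) and rho was -0.84 (exact permutation p = 0.0667). By 4 h the mean had covered 75.0% of the fall reached at 10 h. With spacer means set equal, r was -0.60 over the 8 libraries (exact permutation p = 0.119).

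A further comparison concerned the place of the change along the gene, by ratios within a library that do not depend on scaling between libraries. The 5' external transcribed spacer held 13.0% ± 0.62 of the RPA194 signal of the transcribed region at 0 h and 14.4% ± 0.38 at 10 h, 18S held 11.5% ± 1.09 and 10.6% ± 0.17, and 28S held 40.2% ± 1.23 and 39.7% ± 0.34. The ratio of the 5' external transcribed spacer to 28S was 0.332 ± 0.026 at 0 h. Over the treated libraries it differed from 0 h by 0.074 on the log2 scale, as large as the pooled SD of 0.074 (exact permutation p = 0.357). With region medians in place of means this difference was 0.16 (exact permutation p = 0.0357), and without 0 h replicate 2 it was -0.0065. By time the difference in this ratio was 0.0058 at 4 h, 0.049 at 8 h and 0.17 at 10 h (pooled SD 0.088), where the libraries stood at 0.381 and 0.363 against 0.351 and 0.314 at 0 h. Background still enters such a ratio. With the library's spacer mean subtracted, the differences were -0.019, 0.044 and 0.115. The 10 h libraries then stood at 0.356 and 0.334 against 0.331 and 0.306 at 0 h. The ratio of 18S to the 5' external transcribed spacer, chosen after seeing the data, was 1.59 and 1.61 at 10 h against 1.98 and 1.85 at 0 h (log2 difference -0.26, pooled SD 0.049). That difference was -0.0077 at 4 h, -0.090 at 8 h (libraries at 1.71 and 1.90) and -0.12 over the treated libraries (pooled SD 0.086, exact permutation p = 0.286). The difference over the treated libraries was smaller in size without 0 h replicate 1, the library at 1.98. The exact permutation p was 0.333 for both ratios at 10 h, the smallest that 2 against 2 libraries allow.

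Along the 45 bins of 1000 nt, limma called RPA194 lower in 15 bins at 4 h, 17 at 8 h and 16 at 10 h, and higher in none at any of these times (16, 17 and 16 bins had an unadjusted p under 0.05). The 3 contrasts share their 0 h libraries. At 8 h, 14 of the 17 bins lay within the first 15000 nt and the other 3 above position 41000, with log2 changes from -0.87 to -0.46. The bins not called were not shown to be unchanged. At 8 h all 45 bins had a log2 change below 0 (median -0.52), and the intergenic spacer changed by -0.46 (pooled SD 0.55). At 4 h 44 bins were below 0, and at 10 h 18 were. The largest falls at 8 h were in the bins 44001 to 45000 in the enhancer repeats (-0.87, SE 0.12), 4001 to 5000 at the 5' end of 18S (-0.85, SE 0.14) and 5001 to 6000 in the rest of 18S (-0.85, SE 0.13), each with a limma adjusted p of 0.0066. The 8 h count was 44 without 0 h replicate 2, 0 without 8 h replicate 1 (lowest adjusted p 0.0519). The 4 h count was 0 without 0 h replicate 2, 4 h replicate 1, 10 h replicate 1 or 10 h replicate 2, and 0 at a threshold of 0.01. At 10 h, 23 bins were higher and 16 lower without 0 h replicate 1. With spacer means set equal the count was 0 at each time (2, 0 and 6 bins at an unadjusted p under 0.05).

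To ask whether the initiation factor RRN3 is lost, its libraries at 8 h were compared with 0 h. RRN3 signal was lower at 8 h along the whole unit. In the 47S promoter it went from 37.1 ± 3.33 to 22.8 ± 3.93, a log2 change of -0.71 (pooled SD 0.20; ratio 0.612, with ratios of single libraries from 0.508 to 0.737). In the spacer promoter it went from 8.902 ± 0.84 to 5.36 ± 0.76 (-0.73), and in the enhancer repeats from 7.26 ± 0.43 to 4.40 ± 0.51 (-0.72). The intergenic spacer, where no enrichment lay, went from 1.62 ± 0.050 to 1.06 ± 0.15 (-0.61, pooled SD 0.14). Both 8 h libraries lay below both 0 h libraries in each of these regions, with the exact permutation p at 0.333, the smallest that 2 against 2 libraries allow.

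With limma, RRN3 was lower at 8 h in 45 of 45 bins, with log2 changes between -0.82 and -0.49. All 45 bins had 1 shared SE from the same 2 against 2 libraries. A shift shared by all bins of a library could give every call, so the count adds no evidence to the region values. The largest falls were in the bins 1 to 1000 (-0.82, SE 0.17), 7001 to 8000 (-0.77, SE 0.17) and 8001 to 9000 (-0.75, SE 0.17). The ratio of the 47S promoter to the intergenic spacer was 21.0 and 24.9 in the 0 h libraries and 22.0 and 21.0 in the 8 h libraries, and with spacer means set equal the promoter change was -0.087 (pooled SD 0.13) and limma called 0 bins (1 at an unadjusted p under 0.05). The count was 18 without 0 h replicate 1 and 27 without 0 h replicate 2.

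TAF1B was compared in the same way, as the factor of SL-1 that marks the promoter itself. In the 47S promoter it was at 56.2 ± 13.7 at 0 h and 54.7 ± 0.16 at 8 h, and in the spacer promoter at 23.8 ± 4.93 and 23.3 ± 0.15. The log2 changes were -0.016 (pooled SD 0.25; ratios of single libraries from 0.829 to 1.18) and -0.013 (pooled SD 0.21), less than the spread between replicates. The exact permutation p was 1 for both. As 0.333 is the smallest possible with 2 libraries per time, no change of any size could pass, and the test excludes none. limma called 0 of 45 bins (5 at an unadjusted p under 0.05). In the intergenic spacer it was at 0.895 ± 0.094 and 1.046 ± 0.017, with both 8 h libraries above both at 0 h (0.22). With spacer means set equal 15 bins were called lower and the promoter change was -0.24 (pooled SD 0.14), while without 0 h replicate 1 limma called 17 bins higher.

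UBTF was compared over the transcribed region and the promoter. In the transcribed region it was at 37.0 ± 12.7 at 0 h (libraries at 28.1 and 46.0) and 50.3 ± 11.5 at 8 h (libraries at 58.4 and 42.1). The log2 change was 0.46 with a pooled SD of 0.43 (ratios of single libraries from 0.916 to 2.08, exact permutation p = 0.667). In the 47S promoter it was at 27.3 ± 9.11 and 34.1 ± 6.95, a log2 change of 0.34 (pooled SD 0.40, exact permutation p = 0.667). In the enhancer repeats it was at 47.2 ± 16.1 and 60.1 ± 11.5 (0.38, pooled SD 0.40). The ranges of the 0 h and 8 h libraries overlapped in these 3 regions, and limma called 0 of 45 bins (0 also at an unadjusted p under 0.05). Relative to the intergenic spacer the transcribed region stood at 41.0 and 45.2 at 0 h and 44.9 and 39.9 at 8 h, and with spacer means set equal the log2 changes were -0.022 (pooled SD 0.11) in the transcribed region and -0.14 (pooled SD 0.084) in the promoter. The change depended on the 0 h library kept: the median log2 change over the 45 bins was 0.17 without 0 h replicate 1 and 0.71 without 0 h replicate 2.

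**Figure D3:**
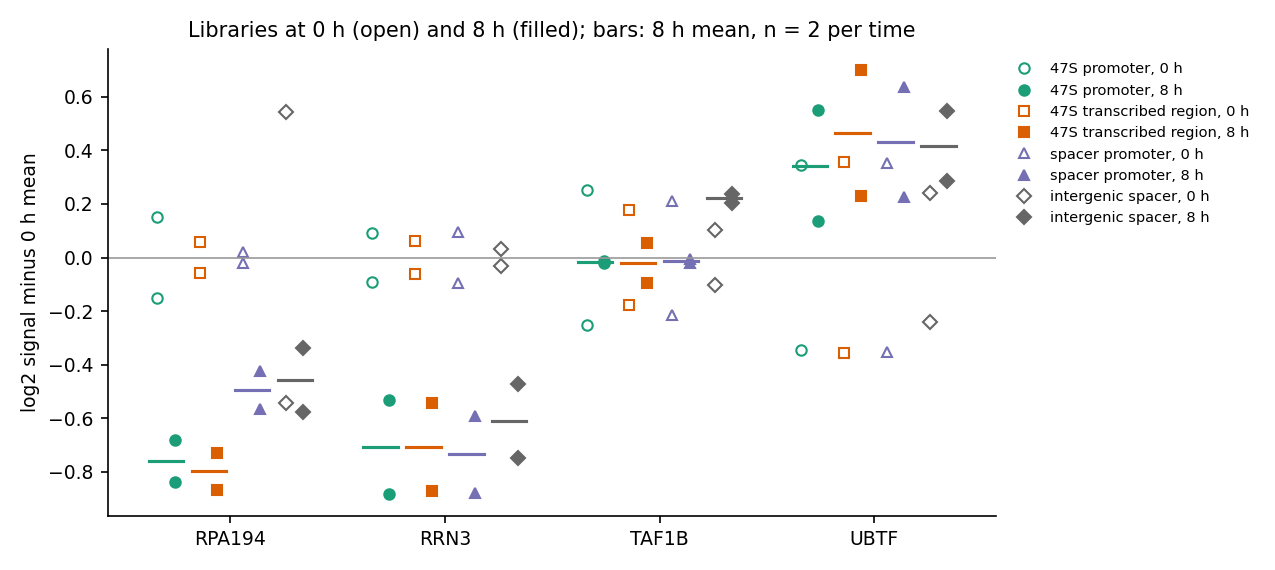
Log2 signal of each library at 0 h (open) and 8 h (filled) minus the 0 h mean (y axis) for 4 regions of each antibody (x axis); bars are the 8 h mean, n = 2 per time. RPA194 and RRN3 promoter values at 8 h lie below 0 h (means -0.76 and -0.71). TAF1B at 8 h lies within the 0 h libraries in all regions but the intergenic spacer, where both are above (0.22). UBTF libraries of both times overlap in all regions but the intergenic spacer. In the intergenic spacer RRN3 is lower too (-0.61), and the RPA194 mean is lower (-0.46) with overlapping libraries.

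The 8 h changes at the 47S promoter were then compared between antibodies. RPA194 and RRN3 changed by -0.76 and -0.71, TAF1B by -0.016 and UBTF by 0.34. The change of RPA194 differed from that of RRN3 by -0.050 (pooled SD 0.26, exact permutation p = 0.889), from that of TAF1B by -0.74 (pooled SD 0.30, exact permutation p = 0.222) and from that of UBTF by -1.10 (pooled SD 0.44, exact permutation p = 0.111). RRN3 differed from TAF1B by -0.69 (exact permutation p = 0.222) and from UBTF by -1.05 (exact permutation p = 0.111). TAF1B differed from UBTF by -0.36 (exact permutation p = 0.500). No pair passed, the lowest adjusted p over the 6 pairs was 0.333, and the smallest p that 36 joint splits allow is 0.0556. With spacer means set equal, RPA194 differed from TAF1B by -0.022 and RRN3 from TAF1B by 0.16.

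The CEBPA-FLAG library gave the FLAG signal along the unit, in 1 library without a replicate check. The series held no FLAG pulldown from untagged or dTAGV-1 treated cells, so background of the FLAG antibody cannot be told apart from CEBPA. The signal was highest in a sharp peak in 18S. Its highest point, at position 5482, was 55.6 times the library's median (exact Poisson interval at 95% from 52.8 to 58.6), where IgG stood at 0.824 (0.622 to 1.07) and Input at 0.678 (0.484 to 0.923). It was 67.5-fold over IgG and 82.0-fold over Input, and the signal was above 50% of the peak from 5444 to 5519, a width of 76 nt. The bins of 1000 nt with the highest ratio to IgG were 5001 to 6000 in 18S (7.51), 9001 to 10000 in 28S (2.82) and 7001 to 8000 in the internal spacers (2.18).

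CEBPA-FLAG stood at 2.35 times IgG over the transcribed region and at 1.97 times with the bin of the peak left out, with each library scaled to its own median. It was 1.83 times IgG in the 5' external transcribed spacer, 2.05 in 28S and 1.57 in the spacer promoter. It was 0.947 times IgG in the intergenic spacer, 0.696 in the 47S promoter and 0.500 in the enhancer repeats. Against Input the ratios were 2.33 in the transcribed region, 0.861 in the intergenic spacer, 0.896 in the 47S promoter and 0.573 in the enhancer repeats, and IgG itself stood at 0.994 times Input in the transcribed region.

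**Figure D4:**
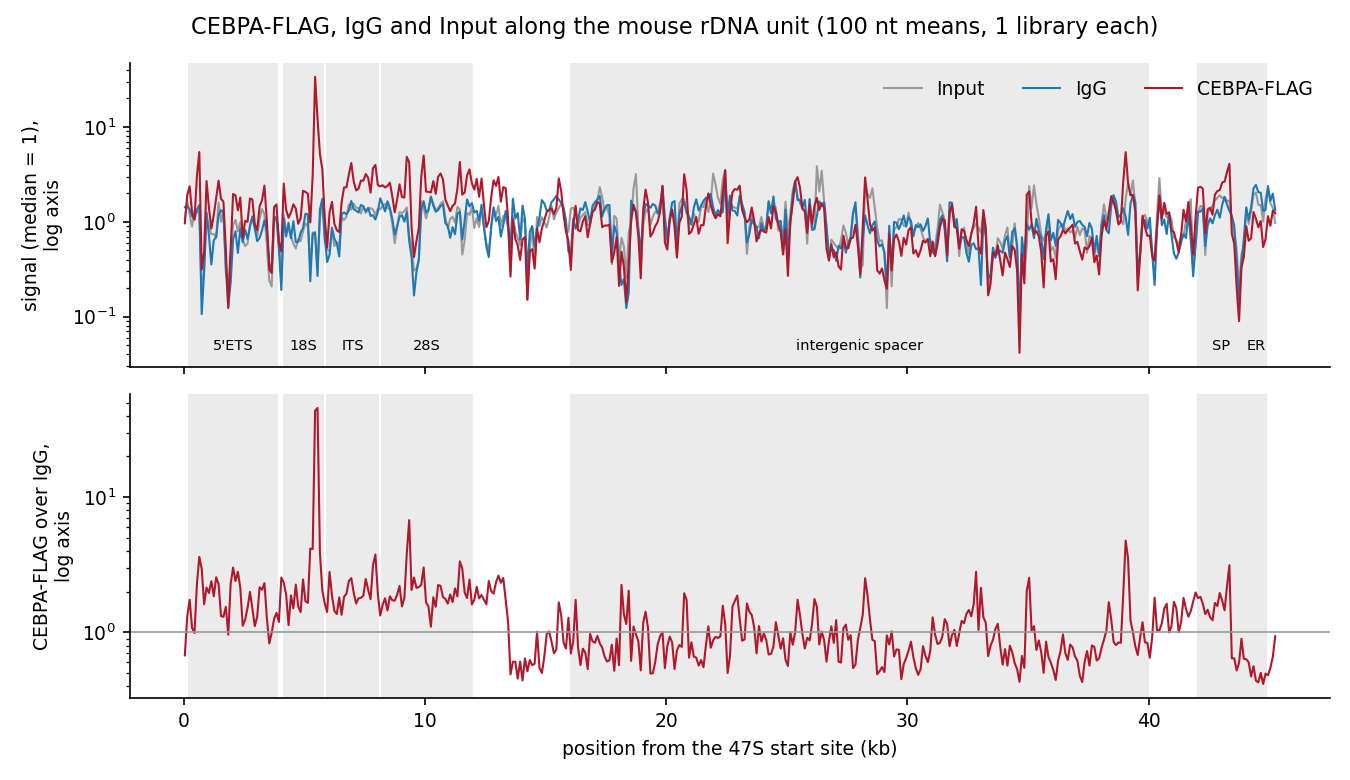
Signal of the Input, IgG and CEBPA-FLAG libraries (upper panel, each with a median of 1, log axis) and the ratio of CEBPA-FLAG to IgG (lower panel, log axis) in 100 nt means against position (x axis, kb), 1 library each. The bins 5401 to 5500 and 5501 to 5600 in 18S reach 43.6 and 45.6 times IgG, and the ratio over the whole transcribed region is 2.35.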

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

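In 2 regions, all libraries of one antibody were lower at 8 h than at 0 h while all libraries of another were higher. In the terminator and downstream, where UBTF libraries stood at 17.4 and 12.6 at 8 h against 7.91 and 12.6 at 0 h, the log2 change of RPA194 minus that of UBTF was -1.27 and that of RRN3 minus that of UBTF was -1.17. In the intergenic spacer, the change of RRN3 minus that of TAF1B was -0.83 and that of RRN3 minus that of UBTF was -1.03. In an exact permutation test chosen after the values were seen, each had p = 0.0556, the smallest that 36 joint splits allow and the value that libraries moving wholly apart always give (adjusted p = 0.303 over the 60 differences of 6 pairs in 10 regions). The highest UBTF library at 0 h and the lowest at 8 h in the terminator were 12.574 and 12.595.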

How the results depend on the processing

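The crossed replicate block, and the other settings of the within-library ratios than that of the 5' external transcribed spacer to 28S, were chosen after seeing the data. Medians, no pseudocount or 10%, boundaries moved by 200 nt, background subtraction and positions of low Input left out kept the direction and the call of the RPA194 changes and of the trend. Setting spacer means equal changed the following results. The log2 change of RPA194 was then -0.68 in the transcribed region (p = 0.214 in the exact permutation test) and -0.60 in the promoter, and r with hours was -0.60. At 4, 8 and 10 h it was -0.57, -0.30 and -1.17 in the transcribed region, and -0.46, -0.27 and -1.07 in the promoter. This alternative divides by a spacer mean that differed between 3.82 and 1.67 in the 0 h libraries and ranged from 1.63 to 3.04 in the treated ones, and the pooled SD in the transcribed region went from 0.085 to 0.52. The promoter change of RRN3 was then -0.087 and that of UBTF -0.14, that of UBTF in the transcribed region was -0.022, and the promoter differences were -0.022 for RPA194 minus TAF1B, -0.12 for RPA194 minus UBTF, 0.16 for RRN3 minus TAF1B and 0.055 for RRN3 minus UBTF. The cause was not tested here beyond the weighing of scale factors among the other observations. The median log2 change of all bins at 8 h moved from -0.52 to -0.059 for RPA194, from -0.63 to -0.015 for RRN3, from 0.16 to -0.058 for TAF1B and from 0.43 to 0.0014 for UBTF.

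The count of changed bins at 8 h in limma was 0 for RPA194 and RRN3 and 15 for TAF1B with spacer means equal. In bins of 500 nt it was 33 of 91 for RPA194 and 91 of 91 for RRN3. In bins of 100 nt it was 161 of 451 for RPA194, 426 of 451 for RRN3 and 1 of 451 for TAF1B, which follows the number of bins tested. With 1 replicate left out, and its lone partner assumed to vary like the others, counts ranged from 0 to 44 for RPA194, 18 to 45 for RRN3, 0 to 17 for TAF1B and 0 to 15 for UBTF. The RPA194 change ranged from -0.87 to -0.75 in the transcribed region and from -0.88 to -0.57 in the promoter, and passed except without a 0 h library, where 7 splits allow no p below 0.143. The ratio of the 5' external transcribed spacer to 28S ranged from -0.0065 to 0.15 and was 0.16 with medians, past the threshold. The ratio of the 47S promoter to the transcribed region ranged from -0.015 to 0.175.

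Replicate numbers showed no steady pairing of the libraries. With 2 libraries per time this cannot show whether same-numbered libraries shared a culture or batch. Deviations of same-numbered RPA194 libraries correlated between -0.94 and 0.94, and those of RRN3, TAF1B and UBTF at -0.19, -0.15 and -0.75. With the replicate block the RPA194 changes stayed at -0.81 and -0.72 (p = 0.0625 in the exact test, the smallest that 16 arrangements allow), and limma called 16 bins for RPA194, 45 for RRN3 and 0 each for TAF1B and UBTF. With crossed numbers it called 45 for RRN3, 0 for TAF1B and 45 for UBTF. Of the values under alternatives other than a replicate left out, 138 had the same outcome, 26 moved, 6 were weaker, 1 was stronger and 3 reversed. With a replicate left out, 113 had the same outcome, 11 moved, 6 were weaker and 2 reversed. With 2 libraries per time, the exact permutation test of the RRN3, TAF1B and UBTF regions cannot go below p = 0.333.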

Other observations

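The ratios within RPA194 libraries at the CEBPA-FLAG peak and the spacer promoter were chosen after the results were seen. So was the use of each value below to weigh an explanation. The trend without 0 h libraries and equal spacer means were set before the data were examined. CEBPA-FLAG had smaller local maxima besides the peak in 18S, chosen after their values were seen, in 1 library with no replicate. In bins of 100 nt, the ratio to IgG was 6.76 at 9301 to 9400 in 28S, 4.77 at 39001 to 39100 in the intergenic spacer, 3.76 at 7901 to 8000 in the internal spacers, 3.62 at 601 to 700 in the 5' external transcribed spacer, 3.35 at 11401 to 11500 in 28S and 3.14 at 43301 to 43400 in the spacer promoter. Against Input these bins stood at 5.90, 3.08, 3.36, 4.31, 3.17 and 2.44, and at 39001 to 39100 IgG itself was 0.645 of Input. Within RPA194 libraries, the bin of 1000 nt that holds the CEBPA-FLAG peak (5001 to 6000) was compared with its neighbouring bins. It held 0.934 and 0.887 of their mean at 0 h and 0.876 and 0.872 at 10 h. The difference between treated and 0 h libraries was -0.034 on the log2 scale (pooled SD 0.034, exact permutation p = 0.250), so no change of the whole bin was detectable. The peak itself was 76 nt wide, so a change limited to it would be diluted in this bin. Whether polymerase changed locally at the peak cannot be told from these values.

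RPA194 was retained more at the spacer promoter, a second start site upstream of the enhancer repeats, than in the transcribed region. In a window of 400 nt at the highest TAF1B signal of 0 h (43038 to 43437), with the library's spacer mean subtracted, RPA194 stood at 0.484 and 0.485 of the transcribed region at 0 h and between 0.568 and 0.700 in the 6 treated libraries. The log2 difference was 0.41 (pooled SD 0.043, exact permutation p = 0.0357, the smallest of 28 splits). Over the whole region of 42000 to 44000 the difference was 0.33 with means and 0.073 with medians (exact permutation p = 0.357).

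For the fall of RPA194, the value of 0.41 argues against 1 scale factor per library as the whole cause, since such a factor leaves ratios within a library where they were. The ratio of the 47S promoter to the transcribed region moved less, as a shared factor would also leave it. With the spacer mean subtracted, its log2 difference from 0 h was 0.093 at 4 h, 0.030 at 8 h and -0.0078 at 10 h. A scale factor may still account for the part of the fall that the same window shares, where RPA194 changed by -0.41 (pooled SD 0.11) against -0.81 in the transcribed region, both without subtraction. The intergenic spacer, which would have to fall with it, changed by -0.12 with a pooled SD of 0.45, so the shared part and such a factor cannot be told apart. A loss that goes on with hours of CEBPA degradation is a candidate explanation: r with hours was -0.87 over the treated libraries alone (exact permutation p = 0.0444), although rho had p = 0.0667, each time had 2 libraries, and with spacer means set equal the changes at 4, 8 and 10 h were -0.57, -0.30 and -1.17.

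For RRN3, loss from the promoters alone is argued against by the intergenic spacer, which changed by -0.61 (pooled SD 0.14). A scale factor shared by all positions of a library, such as a difference in spike-in recovery or pulldown yield, may account for it. With spacer means set equal the promoter change was -0.087, within its pooled SD of 0.13. A loss of RRN3 from the whole unit alike cannot be told apart from such a factor, as each library has 1 scale and 1 treatment, and the log2 change varied over the 45 bins by an SD of 0.076. The spacer signal of RRN3 followed Input (Pearson's r from 0.715 to 0.735 per library), as background does. Such a loss would thus have to include signal where no enrichment lay. Evenly spread RRN3 would also follow Input, so r does not decide between them. The smallest step between neighbouring values was 0.000238 and 0.000242 in the 0 h libraries and 0.000153 and 0.000125 in the 8 h libraries. For TAF1B the steps went the other way, from 0.000113 and 0.000123 at 0 h to 0.000125 and 0.000140 at 8 h. If the step follows a library's scale, the RRN3 scale was lower at 8 h, in the same direction as the signal. How much of the RRN3 fall it covers was not computed, and these values do not show its reason.

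For UBTF, a scale factor shared by all positions may explain why its libraries differed as much within times as between them. Setting spacer means equal lowered the pooled SD in the transcribed region to 0.26 of its value, from 0.43 to 0.11, whereas for RPA194 it raised the SD. A gain of UBTF on the transcribed region over the intergenic spacer is argued against by the change over the spacer of -0.022 (pooled SD 0.11), below the 0.46 of the values as deposited. A gain shared by the spacer stays open and was not tested.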
